A study of Mus musculus with 12 samples.

How the data were processed

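Total RNA of mouse embryonic fibroblasts was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample, in 4 groups of 3: S/S mutant cells, the wild type matched to them, L/L mutant cells, and the wild type matched to those. Per the labels, cells were grown in medium with 10% serum until passage 4, held in 0.1% serum for 72 h, and extracted with TRIzol, and the biotin-labelled target was made by the maker's whole-transcript protocol. The deposited values are log2 RMA values, which means background-corrected, normalized between arrays and summarised over the probes of a probe set. The authors made them with Partek according to the design text of the series. The Partek version and the set of arrays normalized together are not stated, and the log2 scale was read from the values, which ran from 2.43 to 14.67. The genome build is not given in the sources used here.

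The value table held 35556 probe sets. The annotation supplied for it gave exactly 1 gene symbol for 21789, several symbols for 1621 and no symbol for 12146. Genes were tested by the probe set with a single symbol, and for the 999 genes with more than 1 such probe set by the one with the highest mean over 12 arrays, which left 19938 genes. No filter on dim values was applied. Of the 19939 Entrez identifiers of the probe sets with a single symbol, 19856 were found in a RefSeq table of the mouse genome. That table gave the order of genes along the chromosome. It also gave the symbols and synonyms by which members of the gene lists were matched to measured genes. Probe sets with several symbols were not analysed here except in the alternative that tests each probe set, and those without a symbol are given as counts after the report.

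Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model with 4 group means was fitted to 12 arrays (8 residual degrees of freedom, 5.19 prior degrees of freedom from the moderated variances). The contrasts were S/S minus its wild type, L/L minus its wild type, the difference between these effects, their mean, and the wild type of the L set minus that of the S set. The last compares the same genotype and measures how far the sets differ in embryos, culture and array handling together. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over 19938 genes within each contrast, and a gene passed at an adjusted p under 0.05. Each value with an error is a mean with its SD over 3 arrays, or a log2 difference with the SE of the model. The number of arrays limits the precision, and no depth applies.

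A total of 26 gene lists with 731 members was written from general knowledge, of which 655 members were measured under their listed or current symbol. The camera test of limma, with a preset inter-gene correlation of 0.01, was applied to 25 lists with at least 5 measured members, and its p-values were adjusted over the 25 lists of each contrast. The lists were pocket proteins with E2F and DREAM components, DNA replication, mitosis, replication-dependent histones, interferon-stimulated genes, chromatin silencing of repeats, and endogenous retroviral and retrotransposon-derived genes. The plan also provided for adding rows annotated as retroviral or retrotransposon sequence to the retroviral list, and none were added. Further lists were p53 targets with CDK inhibitors, senescence-associated secreted factors, extracellular matrix, contractile genes, cholesterol, hypoxia with glycolysis, the unfolded protein and amino acid response, immediate early genes, imprinted genes, germline genes and homeobox cluster genes. The others were adipocyte, skeletal muscle, cartilage and bone, neural, macrophage and blood cell, endothelial and epithelial markers. The last list, sex chromosome genes, was read as values and not tested. Each list was also tested by camera with an estimated correlation and by fry, which asks whether a list moves on balance without comparing it with other genes. Members passing were counted over all genes and adjusted over the list alone.

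The comparisons, the gene lists, the alternatives and the rule for named genes were set before the data were examined, apart from the additions named after the report. Under that rule Rb1 came first. For each mutant it named up to 10 rises and 10 falls of largest size among genes that passed and whose 3 mutant arrays all lay beyond all 3 wild-type arrays. For a mutant with fewer than 20 such genes it added genes of smallest p up to 20, as values without a call. It also named the 4 members of smallest p in each list discussed, the 5 largest differences in each direction between the effects, the genes passing in both mutants, and the 5 largest in each direction between the wild types. In S/S 24 genes passed, so none were added. The genes named for the mean effect are those that passed. Hoxd13 in S/S and Prim1, Pola2, Mcm4 and Orc1 in L/L, outside the 4 of smallest p in their lists, and the S/S genes near Rb1 were chosen after their values were seen.

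The pipeline was tested on simulated data with 19938 genes and the measured spread, with 50 genes moved up or down at random at each of several sizes. At 2-fold 96% of the changed genes were recovered in each contrast, at 1.5-fold 40% in the S/S contrast and 50% in the L/L contrast, and at 3-fold and 4-fold 100%. False calls numbered 10 in the S/S contrast and 8 in the L/L contrast. Raising 1 list called 0 of the other lists. The simulated noise was independent between genes and arrays, so this does not show how often lists of co-regulated genes pass falsely. That noise was also equal in all arrays, while wild-type array 1 of the S set had a wider spread. The adjusted threshold is easier to pass when many genes change together, so recovery may be lower where few genes change.

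Alternatives covered the normalization between arrays (quantile normalization of the deposited values, median centring), filters on dim genes (a mean of at least 6, the upper part of genes by mean), the probe sets tested, the mean of a gene's probe sets, the variance model (trend and robust, array weights), each set fitted alone, the threshold, a block for replicate number, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw probe intensities were not available, so background and normalization could not be repeated from the start.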

Results

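RNA abundance was measured on 12 arrays in mouse embryonic fibroblasts that carried wild-type or mutant Rb1 and had been held in 0.1% serum for 72 h to arrest growth. The arrays formed 4 groups of 3: S/S mutant cells with their matched wild type (the S set), and L/L mutant cells with their matched wild type (the L set). The labels do not say what the S and L alleles change in the protein. Rb1 encodes the retinoblastoma protein, a repressor of E2F-driven genes that is needed for exit from the cell cycle, and the series title names silencing of endogenous retroelements. Array medians lay between 6.85 and 7.01 on the log2 scale, and the number of arrays limits the precision. The labels do not say whether the 3 replicates of a group came from separate embryos or cultures, so the p-values measure only the spread among these samples.

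Wild-type array 1 of the S set stood apart from the other 11 arrays. Its interquartile range was 3.10, against at least 3.39 for each of the others, and the SD of its residuals was 0.325, against 0.0933 to 0.193. Its correlation with the other arrays was 0.955 to 0.974, while the other 11 correlated with each other at 0.977 to 0.995. The X-linked non-coding RNA Xist and 3 Y-linked genes told the sex of the embryos. In array 1 of the wild type of the L set and array 1 of L/L, Xist was 5.06 and 5.41, Eif2s3y was 9.15 and 9.09, Uty was 8.96 and 8.57, and Kdm5d was 7.92 and 7.65. The other 10 arrays had Xist at 10.4 to 11.5 and Eif2s3y at 3.82 to 4.43, a female pattern. Each group of the L set therefore held 1 male array and the S set held none. In the female arrays, which carry no Y-linked genes, Uty read 4.17 to 4.84 and Kdm5d 4.71 to 5.51, the level these probe sets gave without a target. The Kdm5d value of 5.51 came from wild-type array 1 of the S set, which stood apart, and the next highest was 5.17.

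Rb1 RNA itself was present in all 12 arrays. In the wild type of the S set it was 8.34, 8.83 and 8.89 in the single arrays, a mean of 8.68 ± 0.30 (SD, n = 3), and in S/S it was 9.72, 9.58 and 9.35, a mean of 9.55 ± 0.19 (SD, n = 3). The S/S difference of 0.87 (SE 0.17) on the log2 scale had an adjusted p of 0.0976 over all genes and did not pass, although all 3 mutant arrays lay above all 3 wild-type arrays. Adjusted over the list alone, among the pocket protein and E2F genes, Rb1 had an adjusted p of 0.00481. In the L set Rb1 was 9.23, 9.05 and 8.61 in wild type and 9.39, 9.36 and 9.23 in L/L. That difference was 0.36 (SE 0.17, adjusted p = 1). The difference of Rb1 between the S/S and L/L effects was 0.50 and did not pass (adjusted p = 0.779).

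**Figure D1:**
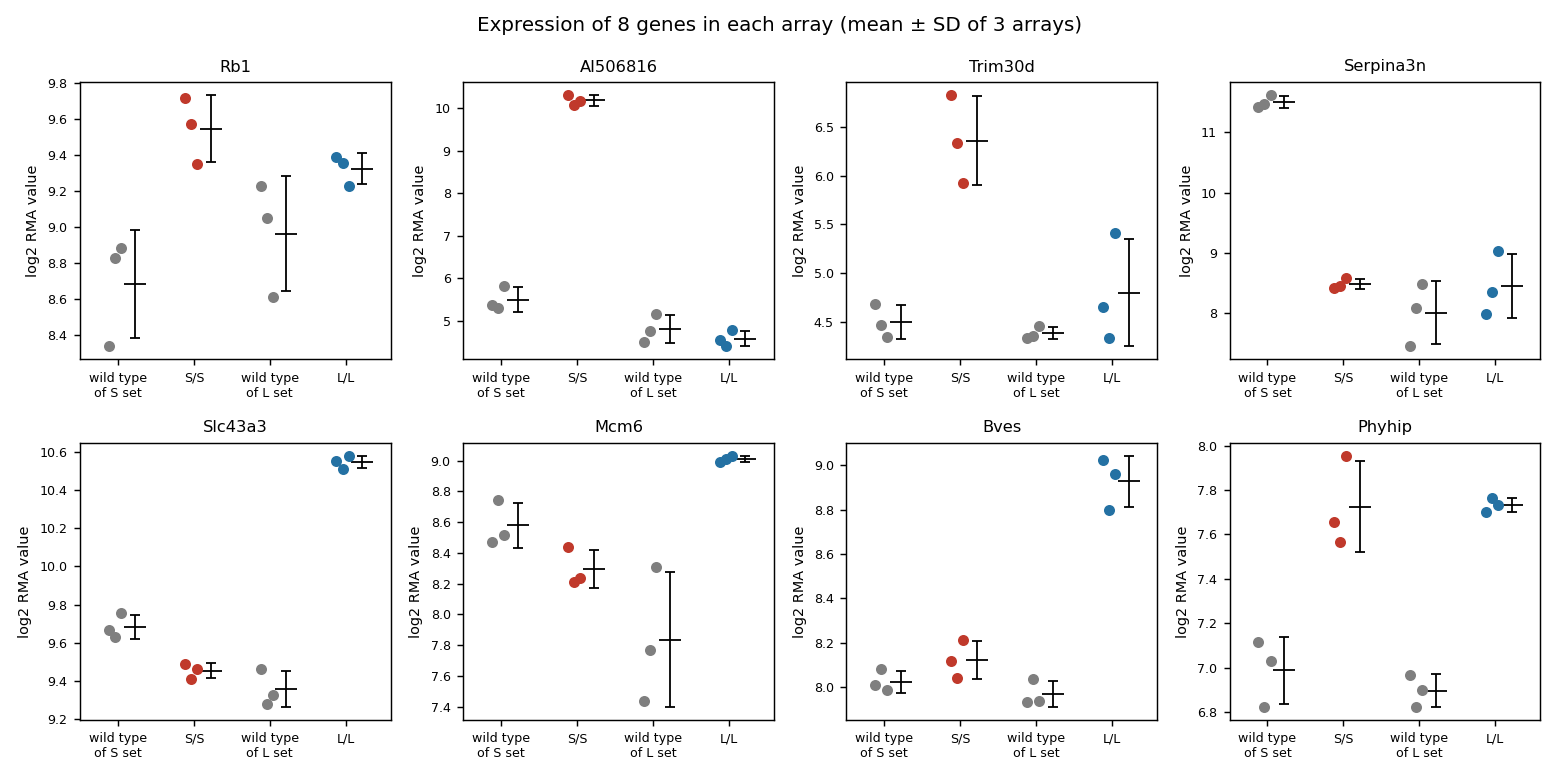
Expression of 8 genes in each array: the vertical axis of each panel is the deposited log2 RMA value, the horizontal axis gives the 4 groups, points are single arrays, and bars are the mean and SD of 3 arrays. AI506816 lies between 10.07 and 10.32 in the S/S arrays and at most at 5.82 in all others, and Slc43a3 lies between 10.51 and 10.58 in L/L and at most at 9.75 elsewhere.

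The first comparison set S/S cells against their matched wild type. The transcript AI506816, an expressed sequence without an assigned function, rose from 5.49 ± 0.29 (SD, n = 3) to 10.19 ± 0.12 (SD, n = 3), a measured difference of 25.95-fold (log2 4.70, SE 0.18, adjusted p = 1.48e-08). It was also low in the L set, at 4.80 in wild type and 4.58 in L/L. These levels lay within the range of the Y-linked genes in female arrays. The mean of the wild type of the S set lay within it only through the Kdm5d value of wild-type array 1 of that set. Background may therefore have compressed the rise. Serpina3n, a secreted serine protease inhibitor of the acute-phase response, fell from 11.50 ± 0.10 (SD, n = 3) to 8.49 ± 0.09 (SD, n = 3), which is 8.07-fold lower (SE 0.25, adjusted p = 0.000204). The S/S level of Serpina3n was close to those of the L set, 8.01 in wild type and 8.46 in L/L. The tripartite-motif gene Trim30d rose by a measured 3.63-fold, from 4.50 to 6.36 (SE 0.25, adjusted p = 0.0162). Its wild-type level was not above that of Uty in female arrays, so background may have compressed this rise too. The interferon-inducible GTPase gene Irgm1 rose by 0.90, from 9.27 to 10.17 (adjusted p = 0.0367).

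In all, 24 of 19938 genes passed the test in S/S, 18 higher and 6 lower, and 2021 genes (10.1%) had an unadjusted p under 0.05. Besides AI506816, Trim30d and Irgm1, the largest rises were those of Gstm6, a mu-class glutathione transferase (3.62-fold), Dgkk, a diacylglycerol kinase (2.57-fold), Olr1, a receptor for oxidised lipoprotein (2.24-fold), and Nup62cl (2.23-fold). The probe sets annotated to the microRNA genes Mir145a and Mir100 rose 2.06-fold and, from a level of 4.89 near that background, 1.91-fold, and the receptor phosphatase gene Ptprz1 rose from 8.77 to 9.77. The adjusted p-values of these genes ran from 0.0162 to 0.0392. The genes that fell with Serpina3n were Lix1 (2.10-fold lower), the alcohol dehydrogenase gene Adh1 (1.92-fold), the melanocortin receptor gene Mc4r (1.87-fold), the neurotrophic ligand gene Artn (1.75-fold) and the nucleotidase gene Entpd4 (1.64-fold). For 14 of the 24 genes the S/S mean lay farther from the arrays of the L set than the wild type of the S set did, and for 10 it was the wild type that lay farther.

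The number of genes passing in S/S changed by over 1.5 times when single arrays were left out. It was 3 without wild-type array 2 of the S set, 3 without S/S array 1, 2 without S/S array 2 and 8 without S/S array 3. It was 38 without wild-type array 1 of the L set, 7 without wild-type array 2 of that set, 11 without L/L array 1 and 13 without L/L array 2 or array 3. Leaving out an array of the L set does not alter the S/S differences. It changes only the estimate of the spread, which the 4 groups share, and its degrees of freedom. AI506816 and Serpina3n passed in all 12 of these fits. Nup62cl, Dgkk and Trim30d passed in 9, Gstm6 in 8, Adh1 and Artn in 7, Mc4r in 6, Irgm1 and Ptprz1 in 4, Olr1, Mir145a, Lix1, Entpd4 and Phyhip, which rose 1.67-fold, in 3, and Mir100 in 2. Without both arrays numbered 1 in the S set, all 24 genes kept their direction and at least 0.772 of their log2 difference, but only AI506816, Serpina3n and Nup62cl passed.

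Among the 25 gene lists tested in S/S, 12 passed with the preset correlation, 6 higher and 6 lower, and 0 passed with camera at an estimated correlation or with fry. Interferon-stimulated genes were higher, with a median of 0.20 and 33 of 40 genes positive (adjusted p = 3.64e-06, 0.568 with an estimated correlation). Markers of macrophages and blood cells, which also express interferon-stimulated genes, were higher by a median of 0.68 in the same arrays. None of the 40 interferon-stimulated genes passed over all genes, and 3 passed adjusted over the list alone. These were the GTPase gene Mx2 (1.03, from a wild-type level of 5.11 in the range of the Y-linked genes in female arrays), the tripartite-motif gene Trim30a (1.71) and Ifi205 (0.66). Genes activated by p53 and CDK inhibitors were higher, with a median of 0.16 and 20 of 28 positive (adjusted p = 7.64e-06, 0.523 with an estimated correlation). Adjusted over the list alone, 7 of them passed against 0 over all genes, among them Perp (0.65), Mdm2 (0.76), which encodes the ligase that degrades p53, Pmaip1 (0.75) and Btg2 (0.45). Smooth muscle and myofibroblast contractile genes had a median of 0.18, with 21 of 23 positive (adjusted p = 3.87e-06, 0.523 with an estimated correlation). Ankrd1 (0.97) was the 1 contractile gene that passed adjusted over the list alone, and Des (0.50) and Myh11 (0.33) did not.

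Imprinted genes were also higher in S/S, with a median of 0.11 and 16 of 21 positive (adjusted p = 0.000316, 0.378 with an estimated correlation). Peg3 (0.44), Peg10 (0.48), Meg3 (0.54) and Nnat (0.45) were the 4 that passed adjusted over the list alone, against 0 over all genes. Immediate early genes had a median of 0.10, with 16 of 26 positive (adjusted p = 0.0404, 0.523 with an estimated correlation), and only Btg2 passed adjusted over the list alone. The immediate early list no longer passed without wild-type array 2 of the S set (adjusted p = 0.164), wild-type array 3 (0.052) or S/S array 3 (0.174). It also failed after quantile normalization, when its median was 0.06 (0.102). It failed at an unchanged median of 0.10 with each set fitted alone (0.0531) and without both male arrays (0.0518). In genes with a mean of at least 6 its median was 0.11 (0.0975) and in the upper part by mean 0.16 (0.0581), also without passing. Macrophage and blood cell markers were higher, with a median of 0.68 and 19 of 21 positive (adjusted p = 6.14e-05, 0.766 with an estimated correlation). None of these markers passed alone, with Itgam at 0.74, Cd68 at 1.22, Cd53 at 1.28 and the embryonic globin gene Hbb-bh1 within the range of the Y-linked genes in female arrays in both groups. Relative to the mean of 12 arrays, the macrophage list had a mean level of 0.44 ± 0.08 in S/S (SD, n = 3) and −0.21 ± 0.10 in its wild type (SD, n = 3). The tests of its genes used a spread shared with the L set, where the list had an SD of 1.05 in wild type and 0.75 in L/L.

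Mitosis genes were lower in S/S, with a median of −0.26 and 37 of 44 negative (adjusted p = 3.05e-05, 0.766 with an estimated correlation). Ncapd2 (−0.43), Cenpa (−0.51), Melk (−0.49) and Cdk1 (−0.39) had the smallest p-values, and 0 of the 44 passed adjusted over the list alone or over all genes. DNA replication genes had a median of −0.16, with 39 of 49 negative (adjusted p = 0.0006, 0.766 with an estimated correlation). Orc1 (−0.37), Chaf1b (−0.42), Tk1 (−0.49) and Fen1 (−0.31) led that list, and again 0 genes passed on either adjustment. Without wild-type array 2 of the S set the mitosis list had a median of −0.20 (adjusted p = 0.0591) and the replication list a median of −0.09 (adjusted p = 0.18). Without wild-type array 3 the replication list had a median of −0.12 (adjusted p = 0.058).

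The other lists that were lower in S/S were cartilage and bone, neural, skeletal muscle and germline genes. Cartilage and bone markers had a median of −0.21 with 12 of 16 negative (adjusted p = 0.0196, 0.523 with an estimated correlation), and the matrix protein gene Matn1 (−0.44) passed adjusted over the list alone. Neural and glial markers had a median of −0.18 with 16 of 22 negative (adjusted p = 0.0214, 0.568 with an estimated correlation), led by Stmn2 (−0.70). Skeletal muscle markers had a median of −0.14 with 20 of 24 negative (adjusted p = 0.00737, 0.766 with an estimated correlation), led by the cardiac actin gene Actc1 (−0.42). Germline genes had a median of −0.14 with 22 of 26 negative (adjusted p = 0.047, 0.766 with an estimated correlation), led by the helicase gene Ddx4. The S/S level of Ddx4, 4.90, was within the range of the Y-linked genes in female arrays, and its wild-type level, 5.44, was near the upper end of that range. Stmn2 and Ddx4 passed adjusted over their lists alone, and no gene of these lists passed over all genes. Without wild-type array 1 of the S set, the array that stood apart, the adjusted p was 0.147 for neural, 0.715 for skeletal muscle and 0.945 for germline genes. The skeletal muscle list (0.0519), the cartilage list (0.1) and the germline list (0.0846) did not pass without S/S array 2. The cartilage list did not pass without wild-type array 2 either, when its median was −0.11 (0.164). The germline list also failed without S/S array 3 (0.174), and without wild-type array 1 (0.0548) or 3 (0.0524) or L/L array 1 (0.0507) or 3 (0.0501) of the L set. After quantile normalization the cartilage (0.105), neural (0.0674) and germline (0.102) lists did not pass, nor in genes with a mean of at least 6 (0.0862, 0.0838 and 0.838).

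The remaining lists did not pass in S/S. The 9 endogenous retroviral and retrotransposon-derived genes with a name on the array had a median of −0.03 (adjusted p = 0.982), and Peg10, shared with the imprinted list, was the 1 that passed adjusted over the list alone. Probe sets without a gene symbol were not part of this list. Of those, 21 were higher and 2 lower in S/S, and what they measure is not given. The 9 named genes therefore do not test retroelements as a whole. Genes for chromatin silencing of repeats had a median of 0.03 (adjusted p = 0.177), with Eed, a Polycomb subunit, at 0.65 and not passing. Pocket protein and E2F genes did not pass as a list (adjusted p = 0.438), although Rb1 and its relative Rbl2 (0.55) passed adjusted over the list alone. The senescence-associated secreted factors (adjusted p = 0.564) held Ereg (0.73) and Cxcl5 (−0.89) passing alone in opposite directions. Homeobox cluster genes (adjusted p = 0.277) held 3 higher and 5 lower adjusted over the list alone, with Hoxb9 (0.49) and Hoxc13 (0.55) higher and Hoxa13 (−0.91) and Hoxd13 (−0.92), which pattern the distal limb, lower. Endothelial markers (adjusted p = 0.982) held 3 higher and 1 lower, with Flt1 at 0.72, Emcn at 1.62, Eng at 0.40 and Egfl7 at −0.31. The adjusted p was 0.14 for replication-dependent histones, 0.438 for extracellular matrix, 0.388 for cholesterol, 0.408 for hypoxia and glycolysis, 0.177 for the unfolded protein and amino acid response, 0.408 for adipocyte markers and 0.0669 for epithelial markers. For 5 of the lists that did not pass, the median and the test differed in sign: pocket proteins, retroviral genes, secreted factors, hypoxia and endothelial markers. The mean and the test differed in sign for the retroviral, secreted factor, extracellular matrix and adipocyte lists.

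**Figure D2:**
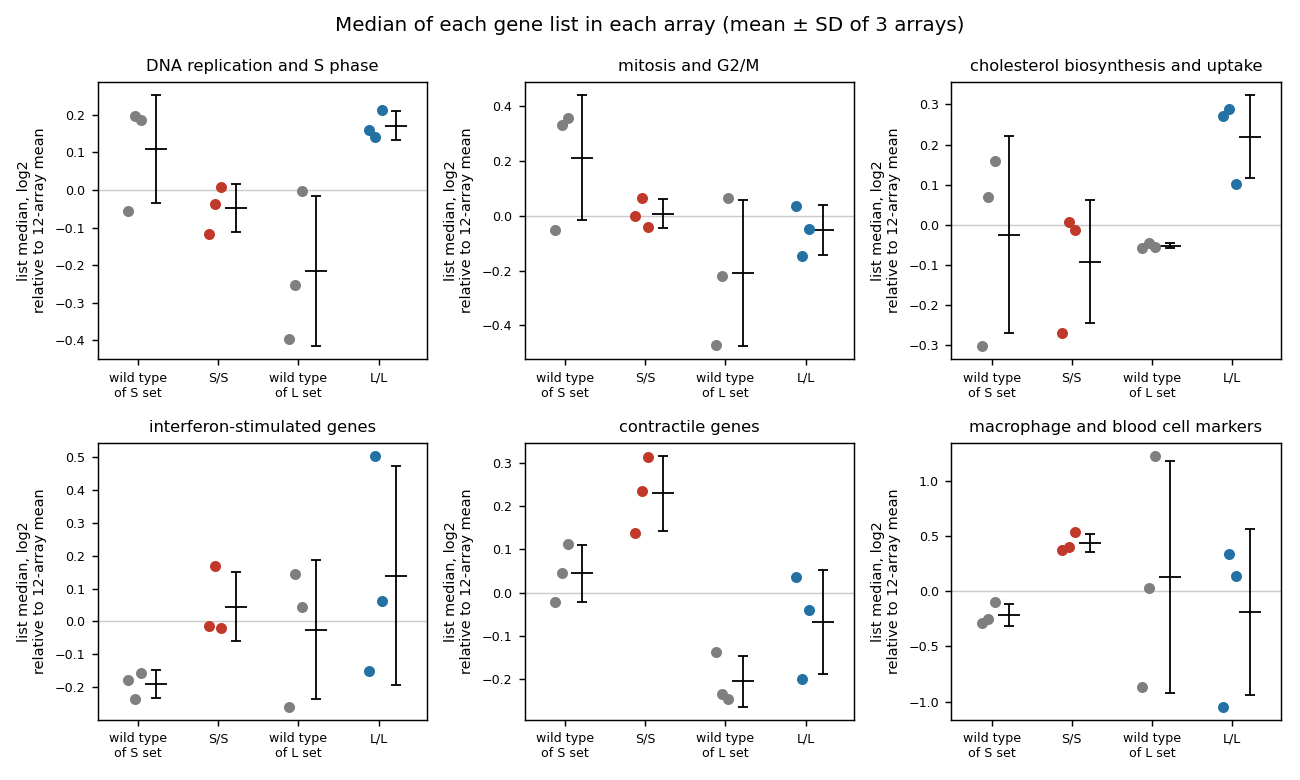
Median of 6 gene lists in each array: the vertical axis is the median log2 level of the list relative to the mean of 12 arrays, the horizontal axis gives the 4 groups, points are single arrays, and bars are the mean and SD of 3 arrays. The replication list is at 0.17 in L/L and −0.22 in its wild type, and the macrophage list spans −0.87 to 1.23 within the wild type of the L set.

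The second comparison set L/L cells against their matched wild type. Slc43a3, a purine transporter gene of the solute carrier family, rose 2.28-fold, from 9.36 ± 0.09 (SD, n = 3) to 10.55 ± 0.03 (SD, n = 3), with a SE of 0.09 (adjusted p = 0.000131). Mcm6, a subunit of the replicative DNA helicase, rose 2.26-fold, from 7.84 ± 0.44 (SD, n = 3) to 9.01 ± 0.02 (SD, n = 3), with a SE of 0.17 (adjusted p = 0.0309). In the S set Mcm6 was 8.58 in wild type and 8.30 in S/S, so the wild type of the L set had the lowest level of the 4 groups. Bves, a membrane protein gene of muscle and epithelium, rose 1.94-fold (adjusted p = 0.00186), and Nsg1, a neuronal trafficking gene, rose 2.04-fold (adjusted p = 0.0128).

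Only 8 of 19938 genes passed in L/L, all 8 of them higher, and 651 genes (3.27%) had an unadjusted p under 0.05. The other 4 were St14, the gene of the membrane protease matriptase (1.91-fold), Phyhip (1.78-fold), Fam81a (1.71-fold) and the glycosyltransferase gene B3galnt1 (1.68-fold), with adjusted p-values of 0.0128 to 0.0226. The 12 genes next in order of p were given as values and did not pass. They included the chromatin assembly gene Chaf1b (0.95), the necroptosis gene Mlkl (0.98), the sodium channel gene Scn3b (0.83), the nuclear body gene Pml (0.62) and the maintenance methyltransferase gene Dnmt1 (0.68). The helicase gene Mcm2 (0.69), the cyclin gene Ccne1 (0.57), Idh2 (0.58), Tbc1d8 (0.63), Nanos1 (0.85), Nrm (0.61) and Spidr (0.54) completed that group, whose adjusted p-values ran from 0.067 to 0.155.

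The L/L count also changed with single arrays. It was 26 without wild-type array 1 of the S set, 3 without wild-type array 1 of the L set, 2 without wild-type array 2 of the L set, 2 without L/L array 1, 4 without L/L array 2 and 2 without L/L array 3. Leaving out an array of the S set changes only the shared estimate of the spread and its degrees of freedom, not the L/L differences. Slc43a3 and Bves passed in all 12 fits that left out 1 array, Nsg1 in 8, St14 in 7, Phyhip and B3galnt1 in 6, Fam81a in 5 and Mcm6 in 3.

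DNA replication genes were higher in L/L. All 49 measured genes of the list were positive, with a median of 0.42 (adjusted p = 2.61e-49, 0.124 with an estimated correlation and 0.127 with fry). Adjusted over the list alone 25 of them passed, against 1, Mcm6, over all genes. Besides Mcm6, Chaf1b, Ccne1 and Mcm2, the primase gene Prim1 was at 1.15, Mcm4 at 0.54, Orc1 at 0.52 and the polymerase subunit gene Pola2 at 0.44. Relative to the mean of 12 arrays, the list was at 0.16, 0.14 and 0.21 in the L/L arrays and at −0.40, −0.25 and −0.00 in the wild type. The L/L mean was 0.17 ± 0.04 (SD, n = 3). In the S set the list was at −0.06, 0.20 and 0.19 in wild type, so that wild-type arrays 2 and 3 lay above L/L arrays 1 and 2, and its mean was −0.05 ± 0.06 (SD, n = 3) in S/S. Without both male arrays the L/L median of the list was 0.29, and without wild-type array 1 of the L set alone it was 0.33.

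**Figure D3:**
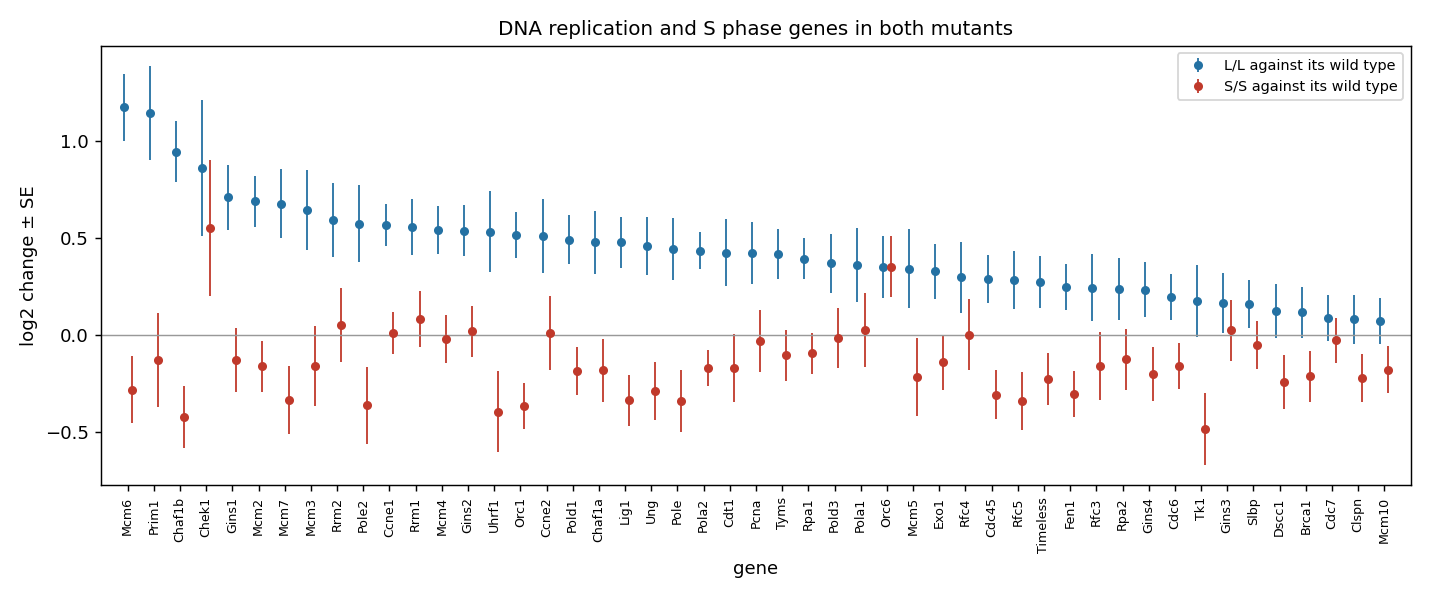
Change of the 49 DNA replication genes in both mutants: the vertical axis is the log2 difference between mutant and matched wild type, the horizontal axis gives the genes sorted by the L/L difference, points are estimates and bars are 1 SE. All 49 L/L estimates are positive, from Mcm6 at the left, while 39 of the S/S estimates are negative.

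Mitosis genes were higher in L/L by less than the replication genes, with a median of 0.17 and 38 of 44 positive (adjusted p = 4.35e-06, 0.533 with an estimated correlation). Cdk1 was at 0.42 and Melk at 0.42, and 0 of the 44 passed on either adjustment. The mitosis list did not pass without wild-type array 1 of the L set, which is a male array, when its median was 0.02 (adjusted p = 0.694). Pocket protein and E2F genes had a median of 0.16 with 14 of 19 positive (adjusted p = 0.000167, 0.209 with an estimated correlation). Tfdp1 (0.38), the E2F dimerisation partner, passed adjusted over the list alone, while Rbl1 (0.61) and E2f1 (0.44) did not. Genes activated by p53 and CDK inhibitors had a median of 0.09 with 23 of 28 positive (adjusted p = 0.000231, 0.533 with an estimated correlation). The death receptor gene Tnfrsf10b (0.44) passed adjusted over that list alone, and the CDK inhibitor gene Cdkn2a (0.37), which responds to loss of pocket proteins, did not.

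All 20 cholesterol biosynthesis and uptake genes were positive in L/L, with a median of 0.22 (adjusted p = 2.21e-08, 0.362 with an estimated correlation). Ebp (0.45), Stard4 (0.45), Insig1 (0.35) and Mvd (0.32) led the list, and 0 of 20 passed on either adjustment. Contractile genes had a median of 0.11 with 18 of 23 positive (adjusted p = 1.42e-05, 0.362 with an estimated correlation), and Mcam (0.51) and Cnn1 (0.52) passed adjusted over the list alone. Immediate early genes had a median of 0.07 with 23 of 26 positive (adjusted p = 0.00219, 0.209 with an estimated correlation), led by the orphan receptor gene Nr4a1 (0.50) and Fosl1 (0.41). Interferon-stimulated genes had a median of 0.14 with 33 of 40 positive (adjusted p = 3.13e-05, 0.533 with an estimated correlation), led by Ifi35 (0.51), Herc6 (0.49) and Tap1 (0.39). The interferon list did not pass without wild-type array 1 of the L set, when its median was 0.02 (adjusted p = 0.378), or without L/L array 2, when it was −0.02 (adjusted p = 0.655).

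Extracellular matrix genes were lower in L/L, with a median of −0.13 and 32 of 36 negative (adjusted p = 3.94e-09, 0.209 with an estimated correlation). Vcan (−0.32), Lum (−0.47), Col3a1 (−0.30) and Dcn (−0.20), which encode proteoglycans and a fibrillar collagen, had the smallest p-values, and 0 of 36 passed on either adjustment. Macrophage and blood cell markers had a median of −0.31 with 19 of 21 negative (adjusted p = 0.000378, 0.568 with an estimated correlation). Their levels varied within groups, from −0.87 to 1.23 in the wild type and from −1.05 to 0.34 in L/L. The macrophage median was 0.27 without wild-type array 3 of the L set (adjusted p = 0.117) and 0.20 without L/L array 1 (adjusted p = 0.305).

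The remaining lists did not pass in L/L. The endogenous retroviral and retrotransposon-derived genes had a median of 0.04 (adjusted p = 0.744), with Peg10 at −0.41 and not passing. Genes for chromatin silencing of repeats had a median of 0.04 (adjusted p = 0.0613), and Chaf1b and Dnmt1 passed adjusted over the list alone. H2bc18 (0.62) passed adjusted over the list of replication-dependent histones (list adjusted p = 0.956), Nnat (0.72) over the imprinted list (0.223) and Tnnt2 (0.51) over the skeletal muscle list (0.492). The list adjusted p was 0.223 for secreted senescence factors, 0.956 for hypoxia, 0.713 for the unfolded protein response, 0.536 for germline, 0.744 for homeobox and 0.0613 for adipocyte genes. It was 0.349 for cartilage, 0.544 for neural, 0.112 for endothelial and 0.487 for epithelial markers. In all, 10 of 25 lists passed with the preset correlation, 8 higher and 2 lower, and 0 passed with camera at an estimated correlation or with fry. The median and the test differed in sign for 6 of the lists that did not pass: histones, retroviral genes, secreted factors, hypoxia, germline and neural genes. The mean and the test differed in sign for the histone, hypoxia, germline and unfolded protein lists.

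The effects of S/S and L/L were then set side by side. Across 19938 genes, which are not independent replicates, the log2 differences had r = −0.0842 and rho = −0.0979, and 44.5% of genes had the same sign in both. The correlation was −0.00623 without wild-type array 1 of the S set and 0.00868 without both arrays numbered 1 of that set, so its size and sign depended on these arrays. Phyhip, whose product binds phytanoyl-CoA hydroxylase, was the 1 gene that rose in both, against 0.00722 expected from the product of both counts over the genes tested. That expectation assumes independent genes, and Phyhip lay 17 places from Rb1 in the order of tested genes. With single arrays left out, Phyhip passed in 3 of 12 fits in S/S and in 6 of 12 in L/L. Its level was 6.99 ± 0.15 (SD, n = 3) and 7.72 ± 0.20 (SD, n = 3) in the S set, and in the L set it rose by 0.83 to 7.73 ± 0.03 (SD, n = 3). Of the lists, 4 passed in both mutants with the same direction (interferon, p53, contractile and immediate early genes), and 3 with opposite directions (replication, mitosis and macrophage genes). With an estimated correlation 0 lists passed in either mutant. In L/L the interferon median was 0.02 without wild-type array 1 and −0.02 without L/L array 2, the mitosis median was 0.02 without wild-type array 1, and the macrophage median was 0.27 without wild-type array 3 and 0.20 without L/L array 1, each without passing. In S/S the replication list did not pass without wild-type array 2 (adjusted p = 0.18) or 3 (0.058), the mitosis list without wild-type array 2 (0.0591), or the immediate early list without wild-type array 2 (0.164), wild-type array 3 (0.052) or S/S array 3 (0.174).

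Only 3 genes differed between the effects by the test of the difference itself, and 1296 had an unadjusted p under 0.05. AI506816 rose in S/S only (adjusted p = 7.04e-07). The size of its difference is not given because the other 3 groups were within or near the range of the Y-linked genes in female arrays. Serpina3n fell in S/S only, with a difference of −3.46 (adjusted p = 0.00161), and Slc43a3 rose in L/L only, with a difference of −1.42 (adjusted p = 0.000511). For Serpina3n the group that lay apart was the wild type of the S set, at 11.50, against 8.49 in S/S, 8.01 in the wild type of the L set and 8.46 in L/L. The count was 21 without wild-type array 1 of the S set, 5 without S/S array 3 and 7 without wild-type array 3 of the L set, and the 3 genes passed in all 12 fits that left out 1 array. After quantile normalization 8 genes passed, 1 positive and 7 negative.

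The difference passed for 7 of 25 lists, 3 positive and 4 negative, and for 0 with an estimated correlation or with fry. Replication genes had the smallest adjusted p, with a median of −0.54 and 48 of 49 negative (adjusted p = 1.33e-26, 0.287 with an estimated correlation). Adjusted over the list alone 26 of them passed, led by Chaf1b (−1.37), Mcm6 (−1.46) and Orc1 (−0.88), against 0 over all genes. Mitosis genes had a median of −0.39 (adjusted p = 1.12e-08, 0.748 with an estimated correlation), and Cdk1 (−0.80) and Melk (−0.91) passed adjusted over the list alone. All 20 cholesterol genes were negative, with a median of −0.27 (adjusted p = 0.000294, 0.748 with an estimated correlation). Macrophage markers had a median of 0.98 (adjusted p = 2.88e-07, 0.748 with an estimated correlation). Imprinted genes had a median of 0.22 (adjusted p = 0.000388, 0.287 with an estimated correlation), led by Peg10 (0.89), and extracellular matrix genes a median of 0.13 (adjusted p = 0.000294, 0.748 with an estimated correlation). Skeletal muscle markers had a median of −0.20 (adjusted p = 0.00866, 0.748 with an estimated correlation). Without wild-type array 1 of the S set the adjusted p was 0.0736 for extracellular matrix and 0.609 for skeletal muscle. It was 0.088 for cholesterol without wild-type array 3 of the S set and 0.0538 for skeletal muscle without wild-type array 3 of the L set. Without L/L array 1, 11 lists passed.

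The mean of both effects passed for 17 genes, 15 higher and 2 lower, and 1109 genes had an unadjusted p under 0.05. Phyhip (0.79, adjusted p = 0.00318), Scn3b (0.84, adjusted p = 0.00651), St14 (0.72, adjusted p = 0.00651), Anks1b (0.60), Dgkk (0.93), Pml (0.50), Irgm1 (0.63) and Pidd1 (0.57), a death-domain gene activated by p53, were higher on average. The other higher genes were AI506816, Slc43a3, Bves, Trim30d, Tshr, Tbc1d8 and Nanos1, and Serpina3n (−1.28) and Mc4r (−0.63) were lower. AI506816 and Serpina3n passed in S/S only and Slc43a3 in L/L only, so their means are not changes shared by both mutants. Bves was at 8.02 and 8.12 in wild type and S/S, against 7.97 and 8.93 in wild type and L/L. Trim30d passed in S/S, while in the L set it was at 4.38 in wild type and 4.80 in L/L. Passing for the mean therefore does not by itself show a change in both mutants. Phyhip, Scn3b, St14, Bves and AI506816 passed in all 12 fits that left out 1 array. The count was 46 without wild-type array 1 of the S set, 11 without its wild-type array 2, and 9 without S/S array 1, 2 or 3. It was 33 without wild-type array 1 of the L set, 5 without its wild-type array 2 and 9 without L/L array 1.

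For the mean effect 13 of 25 lists passed, 9 higher and 4 lower, with 0 at an estimated correlation and 0 with fry. Interferon-stimulated genes (median 0.22, 36 of 40 positive) and contractile genes (0.16, 22 of 23 positive) had the smallest adjusted p, 7.61e-11 (0.329 and 0.225 with an estimated correlation). Genes activated by p53 (median 0.15, adjusted p = 4.68e-09, 0.329 with an estimated correlation), replication genes (0.13, 4.68e-09 and 0.426), immediate early genes (0.08, 0.00107 and 0.225) and pocket protein genes (0.06, 0.00669 and 0.329) were also higher. Passing for the mean does not require the same direction in both mutants. The replication list had a median of −0.16 in S/S and 0.42 in L/L. Cholesterol (0.08, adjusted p = 0.0298), chromatin silencing (0.06, 0.0108) and imprinted genes (0.01, 0.0298) completed the higher lists, while cartilage (−0.11, 0.00979), neural (−0.07, 0.0187), germline (−0.06, 0.0316) and extracellular matrix genes (−0.03, 0.0165) were lower. Without wild-type array 1 of the S set or without S/S array 2, 8 lists passed.

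The last comparison set the wild type of the L set against the wild type of the S set, which carry the same Rb1 genotype. It passed for 1736 genes, 706 higher and 1030 lower, and 4731 genes (23.7%) had an unadjusted p under 0.05. The nuclear non-coding RNA Malat1 was 7.47-fold higher in the L set (adjusted p = 0.00615). It was followed by DQ267102 (log2 1.72), the small nucleolar RNA genes Snord104 (log2 1.68) and Snora31 (log2 1.60) and the tubulin cofactor gene Tbca (log2 1.63). Malat1 was 8.68 ± 1.40 (SD, n = 3) in the wild type of the S set, and 9.17, 11.58 and 11.62 in S/S, the wild type of the L set and L/L. Serpina3n (−3.49), the bone sialoprotein gene Ibsp (−2.36), the sodium channel gene Scn7a (−2.31), Cpa4 (−2.09) and the retrovirus restriction gene Apobec3 (−1.75) were lower. In the wild type of the L set Ibsp, at 4.69, was within the range of the Y-linked genes in female arrays. Scn7a, at 5.48, was near the upper end of that range, so background may have compressed both differences. The Ibsp difference had a SE of 0.68, with an SD of 1.7 in the wild type of the S set, so it may also be smaller than measured. Ibsp passed in 3 of the 12 fits that left out 1 array, DQ267102 in 9, Snora31 and Tbca in 11, and the others in 12. The count was 525 without wild-type array 1 of the L set, 714 without array 2 and 1098 without array 3. After median centring 333 of 1308 genes were higher, and after quantile normalization 915 were higher and 1771 lower.

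Between the wild types 12 of 25 lists passed, 5 higher and 7 lower, with 0 at an estimated correlation and 4 with fry. Mitosis (median −0.41), replication (−0.39), contractile (−0.28), cartilage (−0.21), immediate early (−0.20), neural (−0.19) and skeletal muscle (−0.15) genes were lower in the L set. Over all genes 13 replication and 13 mitosis genes were lower, and adjusted over the list alone 24 and 23. Macrophage (0.31), imprinted (0.18), p53 (0.12), extracellular matrix (0.11) and interferon (0.09) genes were higher in the L set. Fry passed imprinted genes as higher and contractile, immediate early and cartilage genes as lower. Without wild-type array 3 of the L set, 7 lists passed.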

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

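The tests of the arrays numbered 1 in the S set were chosen after the result was seen. So were the number of genes near Rb1 expected by chance and the fit without both male arrays. The same holds for dividing the regroupings over both sets by whether they kept the real grouping of the S set. It also holds for the closer look at the regrouping over both sets that gave the most genes. The other tests in this part were planned.

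Differences between the S/S and L/L effects were singled out where the test of the difference itself passed. For single genes these were AI506816, Serpina3n (−3.46) and Slc43a3 (−1.42). The fitted value of AI506816, 4.92, is no exact amount, since its levels in 3 of the 4 groups were near background. For gene lists the median differences were −0.54 for DNA replication, −0.39 for mitosis, 0.13 for extracellular matrix, −0.27 for cholesterol, 0.22 for imprinted genes, −0.20 for skeletal muscle markers and 0.98 for macrophage and blood cell markers. With an estimated correlation 0 of the 25 lists passed for the difference, and with fry 0. Probe sets without a gene symbol, which the comparisons of the report did not use, also gave a signal. They were tested in a separate fit, with p-values adjusted over all 35556 probe sets. In S/S 23 of 12146 passed, 21 higher and 2 lower, and in the difference between the effects 7 passed, 6 positive and 1 negative. In L/L limma called 0 of them. The 23 probe sets held 13 distinct sets of values, since several share all 12 values, and the 7 held 3. The largest were a group of 4 identical probe sets at 2.96 and a single probe set at −2.93. What these probe sets measure is not given in the sources used here.

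DNA replication genes were higher in L/L than in matched wild type by a median of 0.42. Embryo sex and a single deviating array are argued against as the whole cause, since the median was 0.29 without both male arrays, and the lowest over the 6 omissions of 1 array in the L set was 0.33, without wild-type array 1. The mitosis list had a lower median than the replication list, by a difference of −0.25. Its 95% bootstrap interval over genes was −0.33 to −0.15 from 10000 draws. That interval treats co-regulated genes as independent and carries no spread among arrays. It therefore does not decide whether a larger share of L/L cells passed through the whole cycle. The wild-type arrays of the L set with the lowest replication levels, −0.40 and −0.25, also had the lowest mitosis levels, −0.47 and −0.22, so fewer cycling cells in that wild type remain open as part of the pattern. A direct effect of the L allele on E2F-driven replication genes may account for the pattern and is a hypothesis, untested by other means, and the estimated correlation (adjusted p = 0.124) leaves open whether chance spread of co-regulated genes suffices.

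The 24 genes that passed in S/S were weighed against alleles carried along with the Rb1 locus. Among the 100 tested genes on either side of Rb1, 3 had passed, Htr2a, Phyhip and Entpd4, at 6, 17 and 34 places from Rb1, so linkage to Rb1 is argued against as the cause of the whole set. Those 3 exceed the 0.241 expected by chance (exact hypergeometric p = 0.00172), and 33 of the 200 neighbours (16.5%) had an unadjusted p under 0.05 against 10.1% of all genes. Linked alleles may therefore explain the genes near Rb1 themselves. In L/L 1 of 8 genes, Phyhip, lay among the neighbours (exact hypergeometric p = 0.0775). There 11 neighbours (5.5%) had an unadjusted p under 0.05 against 3.27% of all genes. Whether alleles not linked to Rb1 differed between the cells was not tested.

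Wild-type array 1 of the S set stood apart, and S/S array 1 had the lowest interquartile range, 3.39, of the other 11. Without both arrays 24 of 24 genes kept at least 0.772 of their log2 difference in the same direction. The 24 genes were chosen with both arrays in the fit and for differences large against the spread within groups. Keeping most of the difference was therefore favored by the choice and does not decide whether these arrays contributed. Only 3 of them still passed, with fewer residual degrees of freedom and differences and errors of similar size, as for Trim30d at 1.86 (SE 0.25) with both arrays and 1.72 (SE 0.26) without. Of the 12 lists that passed, 9 still did, and the germline, skeletal muscle and neural lists did not, so those arrays may be the source of these 3. No biological explanation of the array was tested.

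Regrouping the arrays tested whether chance groupings give as much. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In S/S 1 split, the real one, gave as many as 24 genes, and the highest other gave 0, while for lists 1 split gave as many as 12 and the highest other gave 11. In L/L 1 split gave as many as 8 genes (highest other 0), and 3 splits gave as many as 10 lists (highest other 12). Between the wild types 1 split gave as many as 1736 genes (highest other 0), and 5 splits gave as many as 12 lists (highest other 16). In L/L other splits gave medians of larger size for the mitosis, interferon, p53, contractile, immediate early and macrophage lists. None did for the replication (at most 0.28 against 0.42), pocket protein, cholesterol and extracellular matrix lists. In S/S they did for the replication, mitosis, p53, imprinted, germline and skeletal muscle lists, and not for the other lists that passed.

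For the contrasts over both sets 100 splits were drawn. For the difference between the effects 8 splits gave as many as 3 genes (highest other 48), and for the mean effect 3 splits gave as many as 17 genes (highest other 48). All of these kept the real grouping of the S set, and with it the S/S differences, as 12 of the 100 splits did. The 88 splits that changed it gave at most 2 genes in either contrast. The gene counts of these splits are thus no clean reference, and whether chance can be excluded was left open for both counts. For lists, 85 splits gave as many as 7 for the difference (highest other 15) and 11 as many as 13 for the mean effect (highest other 16), so chance could not be excluded there. The 48 genes came in both contrasts from a split that put wild-type arrays 1 and 2 and L/L array 1 of the L set against the other 3, with both male arrays on 1 side. Both of these splits kept the real grouping of the S set, and within the L set alone the same split gave 0 genes. Counts this far above the real ones may reflect a structure of the samples, but for these reasons they do not establish one. This split also ordered the L set by macrophage markers, at medians of −0.87, 0.03 and −1.05 against 1.23, 0.34 and 0.14, and 5 of the 21 genes of that list were among the 48. Of the 25 lists 2 parted the L set in this way, the other being senescence-associated factors. The amount of macrophage transcripts may lie behind the count of this split, and since both male arrays were lowest in it, embryo sex was not told apart from it.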

How the results depend on the processing

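Both number-1 arrays of the S set left out, both male arrays left out and embryo sex as a covariate were added after seeing the data, and the other alternatives were planned. Where a count moved by over 1.5 times, the cause was not tested unless it is named. With all arrays 24 genes passed in S/S, 8 in L/L, 3 for the difference, 17 for the mean effect and 1736 between the wild types.

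AI506816 in S/S passed in 26 of 26 settings, Serpina3n in S/S and Slc43a3 in L/L in 27 of 27, and Bves in L/L in 26 of 27, all but the fit without both male arrays. Mcm6 in L/L passed in 13 of 27, and Rb1 in S/S in 2 of 27. Of 4675 values of single genes 4223 kept their direction and side of the threshold, 326 lost the call, 122 gained it and 4 reversed. The 774 list values cover only lists that passed with all arrays, so none could gain a call. Of these 660 were the same, 110 lost the call and 4 reversed.

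With each set fitted alone S/S gave 44 genes and L/L 5. Quantile normalization gave 8 genes for the difference between the effects and 2686 between the wild types, and median centring gave 12 in S/S. Genes with a mean of at least 6 gave 29 for the mean effect, with 7 lists there and 7 between the wild types. The upper part of genes by mean gave 4 genes in S/S and 6 lists between the wild types, with fewer genes tested. Testing each probe set of the table gave 2 in L/L and 10 for the difference. Array weights gave wild-type arrays 1, 2 and 3 of the S set weights of 0.0774, 5.88 and 0.794, and wild-type array 2 of the L set 3.35. The wild-type means of that fit therefore rested largely on 1 array each. That fit raised the counts to 415 in S/S, 336 in L/L, 293 for the difference, 384 for the mean effect and 6520 between the wild types. An adjusted p under 0.10 gave 60, 14, 8, 42 and 2868 in the same order, by construction, and a minimum of 1.5-fold gave 914 between the wild types.

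With a replicate block S/S gave 37 genes, L/L 5 and the mean effect 29. The labels do not say whether the numbers pair the samples, and the values left it open, so they were treated as sharing only a number. After removal of group means, arrays of the same number correlated at 0.388, 0.475 and −0.122 in the S set and at 0.601, 0.0576 and 0.36 in the L set. Wild-type arrays 1 and 2 of the S set and 1 and 3 of the L set correlated best with the mutant array of their own number, array 3 of the S set and 2 of the L set did not. With the block the adjusted p was 0.0544 for the cartilage, neural and germline lists in S/S. With an estimated correlation 0 lists passed in S/S, 0 in L/L, 0 for the difference, 0 for the mean effect and 0 between the wild types. With fry these numbers were 0, 0, 0, 0 and 4.

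Several lists that passed in S/S did not pass in other settings. Array weights ended the neural (adjusted p = 0.106), skeletal muscle (0.201) and germline (0.802) calls, and in L/L the interferon call (0.228). The neural list did not pass in the upper part of genes by mean either (median 0.16, 0.728). The germline list failed with each set fitted alone (0.062), with the mean of a gene's probe sets (0.0559), without both male arrays (0.0624) and with embryo sex as a covariate (0.061). Without both number-1 arrays of the S set the neural (0.144), skeletal muscle (0.399) and germline (0.531) lists did not pass. For the difference between the effects the skeletal muscle list lost its call with array weights (0.152) and without both number-1 arrays (0.204).

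Without both number-1 arrays of the S set S/S gave 3 genes, L/L 42, the difference 8, the mean effect 37 and the wild types 2870, with 8 lists for the mean effect and 6 between the wild types. The correlation of the effects across genes reversed to 0.00868. Without both male arrays S/S gave 37, L/L 2 (with 13 lists against 10), the mean effect 11 and the wild types 304, and the mitosis list in L/L reversed in the direction of its test, at a median of 0.012. With embryo sex as a covariate S/S gave 42 and the wild types 912.

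Leaving out 1 array gave 2 to 38 genes in S/S, 2 to 26 in L/L, 3 to 21 for the difference, 5 to 46 for the mean effect and 525 to 2078 between the wild types. The lists that passed numbered 9 to 16, 10 to 11, 7 to 11, 8 to 15 and 7 to 13 in the same order. The correlation of the effects ranged from −0.128 to −0.00623. In L/L the macrophage list ranged from −0.78 to 0.27, reversing to 0.27 without wild-type array 3 and to 0.20 without L/L array 1. Its members Adgre1 (−0.93 to 0.060), C1qa (−0.83 to 0.19) and Lyz1 (−0.53 to 0.051) reversed in the same omissions, Adgre1 in both (0.044 without wild-type array 3), C1qa without wild-type array 3 and Lyz1 without L/L array 1. The interferon list in L/L ranged from −0.016 to 0.31 and reversed without L/L array 2. Signal over background limits genes near the lower end of the scale, such as AI506816 and Trim30d in wild type and Ibsp and Scn7a in the L set, where background can compress a difference between groups.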

Other observations

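The genes named here were picked because the mean of both effects passed, so similar values in both mutants were favored by the choice. The sodium channel gene Scn3b, on another chromosome than Rb1, passed at 0.86 in S/S and did not pass in L/L (0.83, adjusted p = 0.0875), and the thyrotropin receptor gene Tshr passed at 0.75 in S/S and not in L/L (0.49). The p53-induced death-domain gene Pidd1 was at 7.99 and 8.65 in wild type and S/S, and at 8.42 and 8.90 in wild type and L/L, and the p53 list had medians of 0.16 and 0.09 (adjusted p = 0.523 and 0.533 with an estimated correlation).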
